A study of Homo sapiens with 2 samples.

How the data were processed

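Total RNA of SW48 cells was extracted with a column kit, amplified and labelled as complementary RNA for Illumina bead arrays, per the labels' protocols. The deposited signal intensity per probe is a mean bead signal that was neither background subtracted nor scaled between the arrays, as the values show. Beside each signal, the deposited table gives a detection p-value against the negative control beads of that array, in steps that correspond to 759 controls. The authors' processed intensity values were a linear function of the deposited signals, with a slope of 1.00 on the control array and 1.20 on the AKBA array and intercepts of -74.7 and -86.5. Both columns had a mean of 352, and their medians were 6.50 and 7.63, so that scale, centring and direction were settled from the values. The software that made these values is not given in the sources used here.

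Signals were corrected and normalized with the neqc function of limma 3.58.1 in R 4.3.3, which infers the background from the detection p, applies a normexp correction with an offset of 16, normalizes by quantiles and takes log2. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A table of the platform's annotation named 1 gene for 28098 probes, several for 13 and none for 20692. Of 28111 probes with a gene, 28059 had an Entrez identifier in the RefSeq table of the GRCh38.p14 assembly, which was used for names only. Each of 18852 genes was represented by the probe with the highest mean normalized signal.

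A probe counted as detected at a detection p under 0.01, and genes detected on at least 1 array were compared. With 1 array per group there is no estimate of the spread between cultures, so no gene was tested and genes were counted at 2-fold. The number of arrays, 1 per group, limits the precision. The probes of one gene give a technical repeat. Of 1677 genes with at least 2 probes detected on both arrays, 995 had other probes in the same direction (59.3%, Wilson 95% interval 57.0 to 61.7%). Of 5 such genes past 2-fold, 4 did (80.0%, interval 37.6 to 96.4%). The genes ASNS, ASS1, C1orf116 and PCK2 had probes in the same direction and SMIM14 did not, and the latter was named after its values were seen. Differences of probes of one gene deviated by a median of 0.20 on the log2 scale.

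Gene lists for stress, chaperones, the cell cycle, DNA methylation, metabolism and cell types were fixed before the data were examined, 35 in all. The median difference of each list, relative to the median of detected genes, was set against 10000 random lists of the same size drawn in 20 bins of mean signal. A list stood apart outside the 2.5th to 97.5th percentile, which about 1 list in 20 of independently drawn genes does by chance. Lists with under 5 detected members were not compared, and their numbers of detected members are given. Percentiles describe these 2 arrays and are not p-values. Named genes were the 12 highest and 12 lowest among genes detected on both arrays, the 5 largest bounds per direction among genes detected on 1 array, up to 4 members of each list that stood apart and up to 2 of others, and DNMT1, DNMT3A, DNMT3B, SAMD14 and SMPD3.

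The alternatives tried were a normexp offset of 50, no background correction, median scaling, loess between the arrays, the authors' processed values, other limits of detection, the mean over the probes of a gene, other folds and 10 bins. Genes detected on 1 array were also set at their bound, in the counts, the lists and the random lists, an alternative chosen after seeing the data. The pipeline was tested on simulated data, a pair of arrays with known changes. Its true signals and background were taken from the control array, and the second array was made dimmer. Signal noise was set at a standard deviation of 0.2 on the log2 scale and was not estimated from the arrays. Of 13324 unchanged probes, 14 passed 2-fold, 88.9% of 3-fold changes were counted and 7.14% of 1.5-fold changes. Of 200 unchanged lists, 6.00% stood apart. Those lists were random draws with independent noise, so this share says nothing of lists whose genes vary together. The simulated background was revised after its output was seen, at first because it detected too many probes and again because too many unchanged probes passed 2-fold. The count of 14 and the shares counted therefore depend on that model and on the noise that was set.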

Results

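Gene expression was measured in SW48, an established human colorectal cancer cell line, with and without acetyl-11-keto-β-boswellic acid (AKBA), a triterpenoid of Boswellia resin. The treated culture had received AKBA at 20 µM for 6 days. The labels conflict on the control, which the treatment protocol gives as dimethyl sulfoxide vehicle at 0.1% and the source name as not treated, so an effect of the vehicle is not excluded from the differences. Each group was represented by 1 Illumina bead array of 48803 probes, so no difference below has a replicate check, no gene was tested, no p-value was computed across genes, and higher and lower describe these 2 arrays. The median bead signal was 80.9 on the control array and 78.3 on the AKBA array, and the mean signals were 425 and 365. The control array detected 12389 probes (25.4%) and the AKBA array 11329 (23.2%), at a detection p under 0.01. Across the 11226 probes detected on both arrays, the log2 signals correlated with a Pearson r of 0.986; this is a correlation across probes, which are not independent replicates.

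The comparison of AKBA with control addresses which genes differ in expression after 6 days of the compound. Among genes detected on both arrays, those furthest above the control, DDIT4, TRIB3 and ASNS, were genes of the integrated stress response. This is the program of the transcription factor ATF4 that cells use when amino acids are short or protein folding is disturbed. DDIT4, an inhibitor of mTORC1 signalling, was 7.15-fold higher, with a signal of 320 on the control array and 1536 on the AKBA array. TRIB3, a pseudokinase that ATF4 induces, was 3.95-fold higher, and asparagine synthetase (ASNS) was 3.67-fold higher. HSPA5, the chaperone BiP of the endoplasmic reticulum, had the largest deficit among genes detected on both arrays, with a log2 difference of -1.32. Its signal was 1390 on the control array and 476 on the AKBA array. DDIT4, TRIB3 and HSPA5 were each measured by 1 named probe, so no other probe checks them. Signals are given as deposited, and folds and log2 differences after normalization, which evens out the lower brightness of the AKBA array.

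Most genes differed little. Of 18852 named genes, 8639 were detected on at least 1 array and 7930 on both. Of the latter, 94.5% lay within 1.5-fold between the arrays, and the standard deviation of the log2 difference across them was 0.30. The normalized signals of 35 genes were higher and of 30 lower on the AKBA array by 2-fold or more, 0.752% of the detected genes. Of the 35 higher genes, 25 were detected on both arrays, against 8 of the 30 lower ones, and the other 10 and 22 were detected on 1 array, where the size of the difference is uncertain. With such genes set at a lower bound of their difference, 29 genes were higher and 8 lower by 2-fold or more. The split depended on the background correction and the scaling of the arrays. An offset of 50 gave 20 higher and 4 lower genes, and no background correction 16 and 2. Scaling to equal medians gave 18 higher and 177 lower genes, with the median of all detected genes at -0.32, and the authors' processed values gave 43 higher and 121 lower, with that median at -0.11. Counted relative to the median of detected genes, median scaling gave 44 higher and 20 lower.

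**Figure D1:**
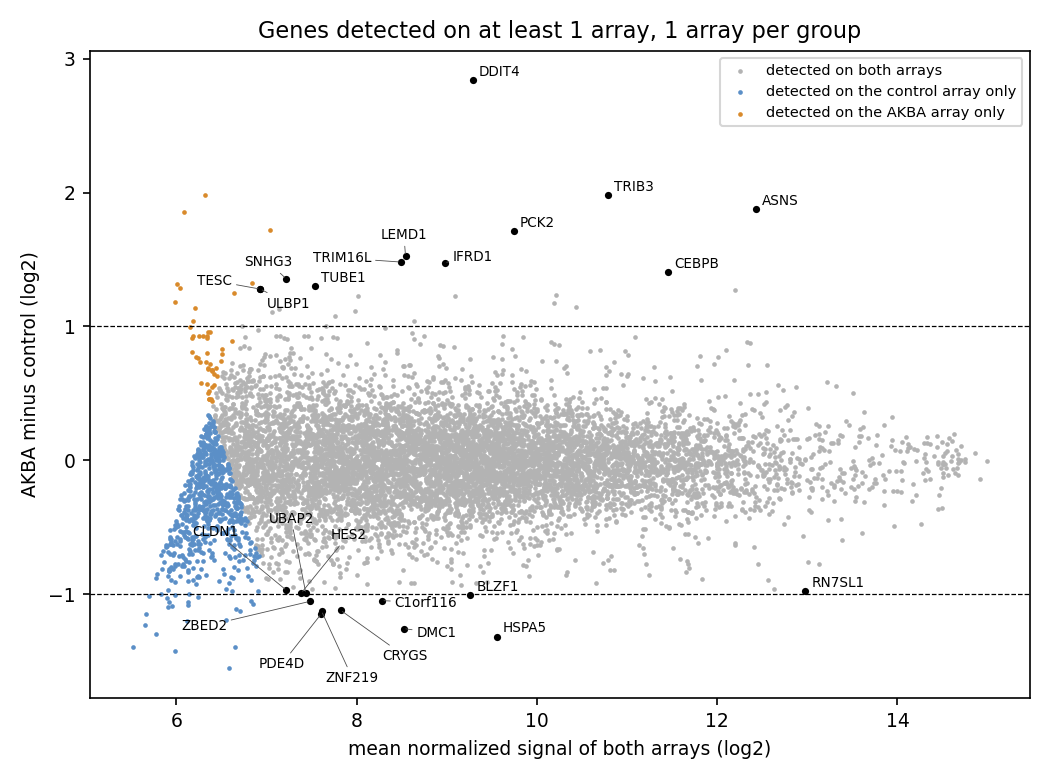
Log2 difference, AKBA minus control, of each of the 8639 detected genes (vertical axis) against its mean normalized log2 signal over both arrays (horizontal axis). Each point is a gene, coloured by the arrays that detected it, dashed lines mark 2-fold, and the labelled black points are the 12 highest and 12 lowest genes detected on both arrays, from DDIT4 at 2.84 to HSPA5 at -1.32.

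Among the other genes at the top of the ranking, PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, was 3.27-fold higher. LEMD1 was 2.88-fold, TRIM16L 2.79-fold and IFRD1 2.78-fold higher. CEBPB, a basic leucine zipper transcription factor, was 2.65-fold higher, with signals of 1985 and 4190. SNHG3, a small nucleolar RNA host gene, was 2.56-fold and TUBE1, epsilon tubulin, 2.46-fold higher. TESC was 2.43-fold higher, as was ULBP1, a ligand of the natural killer cell receptor NKG2D. At the other end, the meiotic recombinase DMC1 stood at -1.26, the cyclic AMP phosphodiesterase PDE4D at -1.15, ZNF219 at -1.13, CRYGS at -1.12, ZBED2 at -1.05 and C1orf116 at -1.05, all on the log2 scale. BLZF1 stood at -1.01, UBAP2 and HES2 each at -0.99, the signal recognition particle RNA gene RN7SL1 at -0.98 and the tight junction gene CLDN1 at -0.97. PDE4D, ZNF219, CRYGS, ZBED2, UBAP2, HES2 and CLDN1 had signals of 152 to 193 on the AKBA array, where the lowest detected signal was 141. On the control array, TESC and ULBP1 each had 145, SNHG3 161 and TUBE1 190, where the lowest detected signal was 138. The sizes of these differences are therefore uncertain and depend on the background correction.

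For genes detected on 1 array, only a bound was taken, with the missing side set at the lowest signal detected on that array or at its own signal, whichever was higher. The glycine transporter SLC6A9 was at least 3.28-fold higher with AKBA, PMEPA1 at least 2.5-fold, CDH23 at least 2.19-fold, DCLK1 at least 2.12-fold and JDP2, an AP-1 family repressor, at least 1.84-fold. In the other direction, WIPI1 was at least 1.79-fold higher in the control, IGSF9 at least 1.78-fold, PHLPP1 at least 1.75-fold, MIGA1 at least 1.74-fold and ONECUT2 at least 1.73-fold. These are bounds under the main background correction only, and their sizes depend on it because the signals lie near the detection limit. SLC6A9, for example, had signals of 138 on the control array and 267 on the AKBA array.

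The list of integrated stress and amino acid response genes had 25 detected members, and all 25 stood above the median of detected genes. Its median difference was 0.84 on the log2 scale relative to that median, and 0 of 10000 random lists of the same size and brightness were as high. With genes detected on 1 array at their bound, the list median was 0.78 and 5 members were higher by 2-fold or more, against a mean of 0.0789 in random lists treated alike. Among members detected on both arrays, DDIT4, TRIB3, ASNS and CEBPB had the largest differences. Serine synthesis was among the functions covered, as were cystathionine metabolism, amino acid transport and the charging of transfer RNAs. Of 7 further detected probes, which belong to 6 genes of the list, 6 lay above 0, from 0.75 for WARS1 to 2.03 for ASNS, and 1 of the 2 further probes of ATF4 did not, at -0.01, where the other gave 0.83 and the brightest 0.50. PCK2, which is outside the list, gave 1.71 and 1.5 with its probes.

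The chaperones of the endoplasmic reticulum, which the unfolded protein response induces, did not share that direction. Of 19 detected members, 13 stood below the median of detected genes, and the list median of -0.12 lay at the 3.65th percentile of its random lists, inside their central range. The list lay below that range, at -0.14 to -0.15, with median scaling, the authors' processed values, no filter on detection or genes of 1 array at their bound. Besides HSPA5, CRELD2 stood lowest, at -0.85. Members also stood on the other side, among them XBP1, a transcription factor of the unfolded protein response, 1.77-fold higher, the sensor ATF6 at 0.45 and the disulfide isomerase P4HB at 0.35; these were named after their values were seen. The heat shock response list lay below its random range, with 12 of 15 members below the median of detected genes. Its median was -0.18, or -0.11 with median scaling and -0.095 with the authors' processed values. BAG3 stood at -0.65, the small heat shock protein gene HSPB1 at -0.42, HSPA1B at -0.35 and HSPE1 at -0.30.

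**Figure D2:**
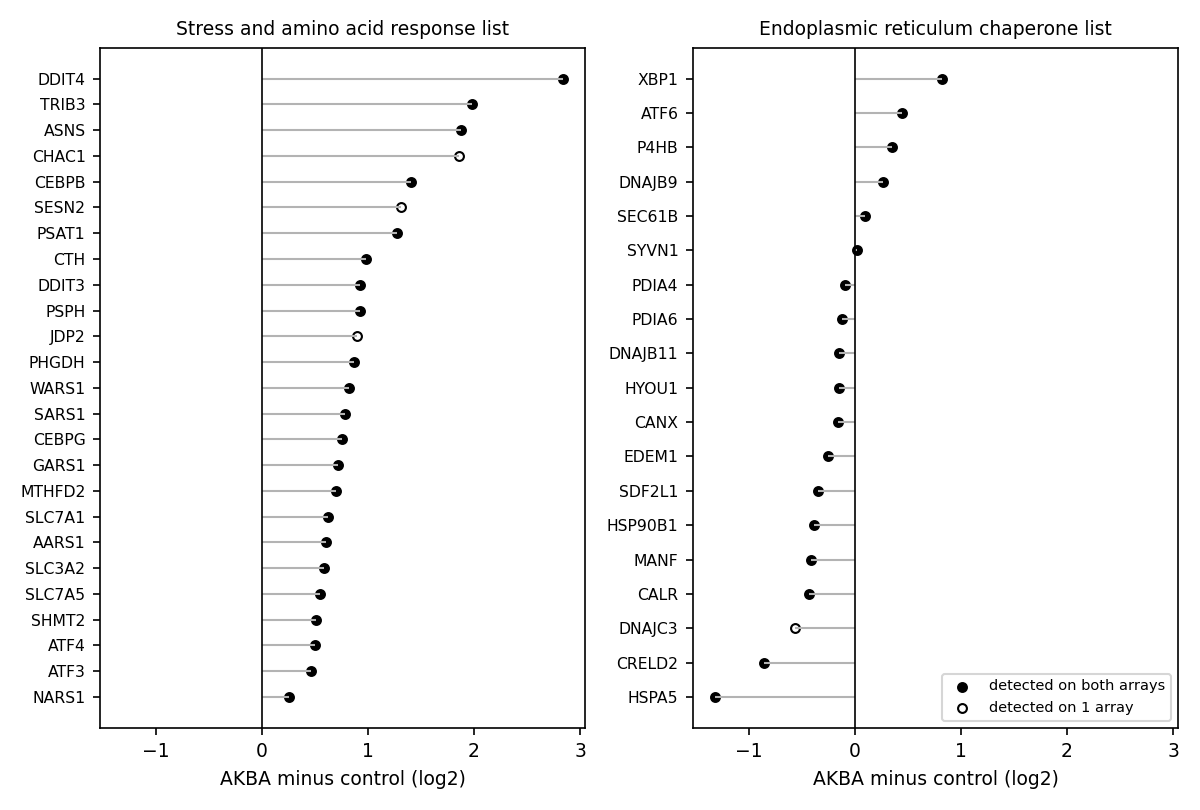
Log2 difference, AKBA minus control (horizontal axis), of each detected member of the stress and amino acid response list (left, 25 genes) and of the endoplasmic reticulum chaperone list (right, 19 genes). Filled points were detected on both arrays and open points on 1 array, where the plotted difference is not a bound, and the 25 stress genes lie to the right of 0 while HSPA5 lies at -1.32.

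Of 27 lists with at least 5 detected members, 6 lay above and 6 below the central range of their random lists. Independently drawn genes would give 1.35 such lists by chance. Genes of one list can vary together between cultures, so more lists than that could stand apart without an effect of AKBA. Immediate early and AP-1 genes, which growth factors and stress induce within minutes, had 22 of 27 members above the median of detected genes and a list median of 0.22. JUN was 1.82-fold, EGR3 1.80-fold, FOSB 1.77-fold and JUND 1.72-fold higher. The list of epithelial junction and keratin genes had 16 of 21 members above and a median of 0.26, which was 0.15 with genes detected on 1 array at their bound. The splicing regulator ESRP1 was 1.90-fold, CLDN7 1.59-fold and the desmosomal cadherin DSC2 1.51-fold higher, while CLDN1 stood at -0.97. Targets of NRF2, the regulator of the oxidative stress response, had 13 of 19 members above and a median of 0.19, and GCLC, the catalytic subunit of glutathione synthesis, was 1.60-fold higher. TRIM16L, ME1 and SRXN1 of the same list were 2.79-fold, 1.5-fold and 1.48-fold higher. The 6 members below included NQO1 at -0.11 and HMOX1, detected on the control array only, both named after their values were seen. Xenobiotic metabolism genes had 8 of 12 members above and a median of 0.23. The transporter ABCC3 was 1.51-fold higher and the sulfotransferase SULT1A1 stood at -0.59. ESRP1 and ABCC3 had signals of 196 and 158 on the control array, where the lowest detected was 138, so their folds are uncertain. The 8 detected canonical histone genes had 7 members above and a median of 0.24, with H2AC18 1.40-fold and H4C3 1.29-fold higher. Without a filter on detection, the NRF2, xenobiotic and histone lists lay inside their random ranges, with medians of 0.051, 0.026 and 0.017. The xenobiotic median turned to -0.17 among genes brighter than the median detected gene, and the histone median to -0.033 at a detection p under 0.05.

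Genes of DNA replication and of mitosis lay lower as groups. Of 30 detected G1/S and replication genes, 24 stood below the median of detected genes, and the list median was -0.15. ORC6, a subunit of the origin recognition complex, stood at -0.60, thymidylate synthase (TYMS) at -0.55, the chromatin assembly factor CHAF1A at -0.54 and the flap endonuclease FEN1 at -0.47. Of 35 G2/M and mitosis genes, 24 stood below and the list median was -0.09, with KIF20A at -0.64, the mitotic transcription factor FOXM1 at -0.44, BIRC5 at -0.43 and CENPE at -0.39. Wnt targets, which mark proliferating crypt cells, had 11 of 16 members below and a median of -0.20, but without a filter on detection the median was -0.051, inside its random range. PTPRO stood at -0.67, SOX4 at -0.59, ZNRF3 at -0.48 and AXIN2, a negative regulator of the pathway that it also reports, at -0.45. Interferon-stimulated genes had 10 of 13 members below and a median of -0.34, or -0.18 without a filter on detection. IFIT2 stood at -0.77, ISG15 at -0.77, IRF9 at -0.74 and IFI6 at -0.61. IFIT2, IRF9 and CHAF1A had signals of 146, 184 and 183 on the AKBA array. The lowest detected signal there was 141, so the sizes of their differences are uncertain.

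**Figure D3:**
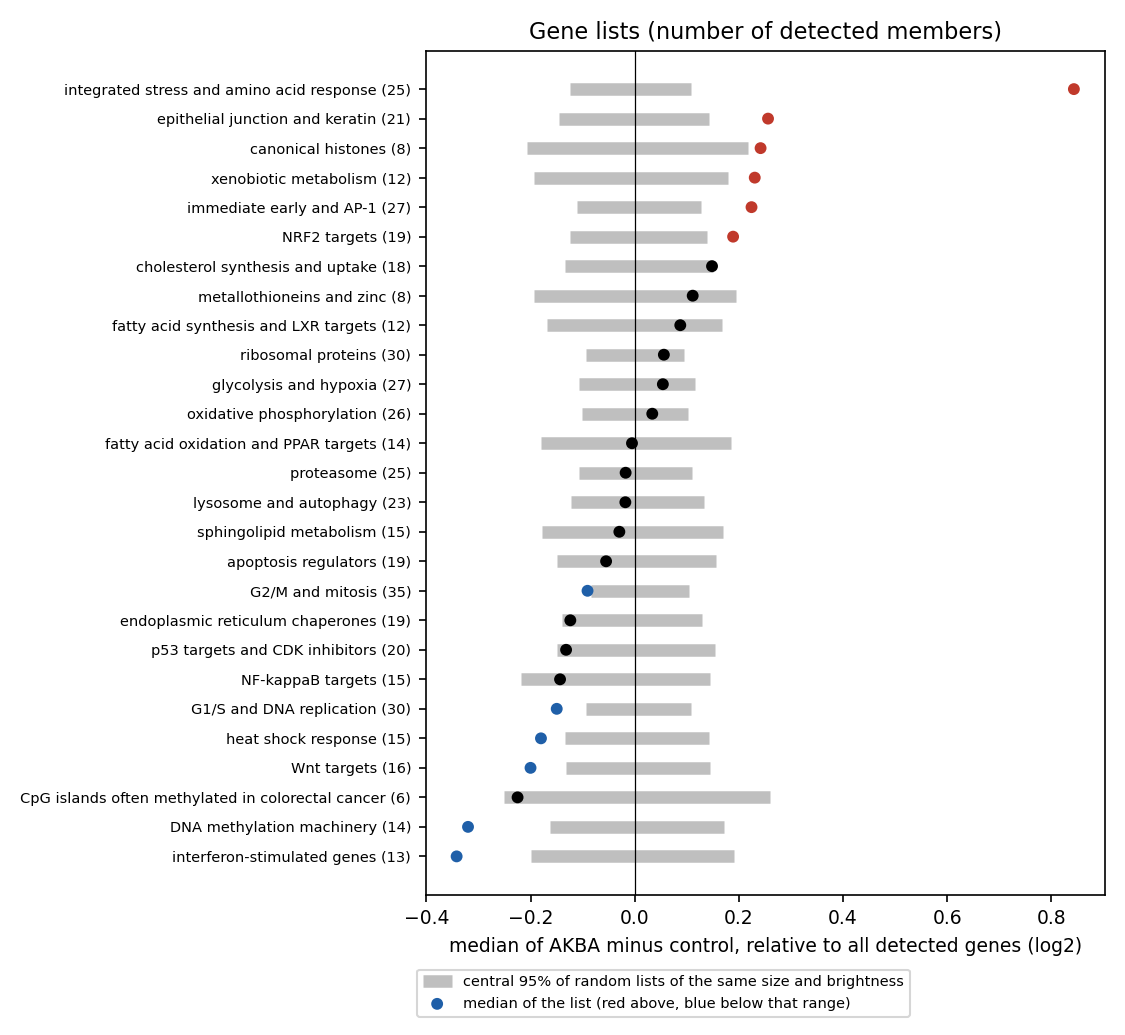
Median log2 difference of each of the 27 gene lists, relative to the median of detected genes (horizontal axis), with the number of detected members in brackets. Grey bars span the central 95% of 10000 random lists matched in size and brightness, and points in red and blue lie above and below them, with the stress and amino acid response list furthest from its bar at 0.84.

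A separate set of genes was fixed before the data were examined because the study concerns DNA methylation. Of 14 detected genes of the methylation machinery, 10 stood below the median of detected genes and the list median was -0.32, with 0 of 10000 random lists as low. With the mean over the probes of a gene it was -0.16, at the 2.14th percentile, and without a filter on detection -0.15, at the 2.11th percentile. DNMT3B, a de novo methyltransferase, stood at -0.70 by the brightest of its 5 probes, with signals of 259 and 155. The latter is near the lowest signal detected on the AKBA array, 141, so the size is uncertain. The maintenance methyltransferase DNMT1 stood at -0.32 with signals of 7699 and 5150, the chromatin remodeller HELLS at -0.49 and UHRF2 at -0.46. The methyl-CpG binding gene MBD2 was 1.48-fold higher, with signals of 184 and 205. UHRF2 had a signal of 194 on the AKBA array, so the sizes for UHRF2 and MBD2 are uncertain as well. DNMT3A was detected on neither array. SAMD14 had a signal of 92.8 on the control array and 105 on the AKBA array, with detection p of 0.0751 and 0.0224. SMPD3 had signals of 81.2 and 96.9, with detection p of 0.192 and 0.0369. Neither gene passed the detection limit on either array, so no fold is given.

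Of 49 genes with CpG islands often methylated in colorectal cancer, 43 were detected on neither array, 5 on both and 1 on the control array only. The 6 detected ones had a median of -0.22, inside their random range, with NDRG4 at -0.66 and RASSF1 at -0.52. RASSF1 had a signal of 189 on the AKBA array, near the lowest detected there, so its size is uncertain. The 5 detected on both arrays had a median of -0.28, below their range at the 2.32nd percentile. Of 26 cancer-testis and germline genes, which are commonly silenced by methylation in somatic cells, 26 were detected on neither array.

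The remaining lists lay inside their random ranges under the main processing. Cholesterol synthesis and uptake had a median of 0.15, metallothioneins and zinc 0.11, fatty acid synthesis and LXR targets 0.09, ribosomal proteins 0.06, glycolysis and hypoxia 0.05 and oxidative phosphorylation 0.03. Fatty acid oxidation and PPAR targets stood at -0.01, the proteasome at -0.02, lysosome and autophagy genes at -0.02, sphingolipid metabolism at -0.03 and apoptosis regulators at -0.05. Targets of p53 with the inhibitors of cyclin-dependent kinases stood at -0.13 and NF-kappaB targets at -0.14. Some of these lists left their ranges under other processing. Ribosomal proteins stood above theirs, at 0.23 with median scaling and 0.24 with the authors' processed values, and apoptosis regulators below theirs, at -0.16 at a detection p under 0.05 and -0.15 with the mean over probes. The p53 targets stood below theirs under 5 alternatives, reaching -0.19 with the mean over probes and -0.23 among genes brighter than the median detected gene, and cholesterol synthesis above its own under 5, at 0.13 to 0.16. Metallothioneins and zinc stood above theirs among the brighter genes, at 0.19. Among these, CYP51A1 of sterol synthesis was 1.70-fold higher, the stress cytokine GDF15 was 1.64-fold higher and TP53I3 stood at -0.91. Lists with too few detected genes were those of eicosanoid synthesis with 4, absorptive enterocyte markers with 4, fibroblast and mesenchymal markers with 3, leukocyte markers with 3, goblet and secretory markers with 2, and enteroendocrine markers and the pair SAMD14 and SMPD3 with 0 each. The cancer-testis list also had 0.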

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

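The probes without a gene name were not part of the planned comparisons, and the tests of brighter members, of further probes and of the reduced methylation list, with all resampled intervals, were chosen after the results were seen, as was the use of the planned loess setting and chaperone list to weigh explanations. Among the 1590 detected probes without a gene name, 18 were higher on the AKBA array by 2-fold or more and 10 lower, and 12 and 3 of these were detected on both arrays. The probe ILMN_2353754 had the highest difference, 1.83 on the log2 scale, with signals of 155 and 329.

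The first pattern is the higher signal of stress and amino acid response genes with AKBA. A scaling difference that varies with intensity was already reduced by the quantile normalization and by random lists matched in brightness. The list median of 0.83 after loess between the arrays could therefore hardly have differed and adds little. Noise of dim probes is argued against by the median of 0.78 over the 19 members brighter than the median detected gene. Both medians had resampled intervals above their random lists. With 1 array per group, resampled intervals here and below hold no spread between cultures. Induction of the endoplasmic reticulum chaperones as a group is argued against by their median of -0.12, whose resampled interval of -0.36 to 0.05 ends below 0.13, the upper limit of random lists; with XBP1 and ATF6 above 0, stress of that organelle without such induction stays open. A count of signs, 6 of 7 further probes above 0 (exact interval 42.1 to 99.6%), left faulty single probes open. By size, a test chosen after that count, the further probes of the 6 genes that have them had a median of 1.04. Its resampled interval was 0.60 to 1.69, against an upper limit of 0.28 in random genes. The further probe of CTH was detected on the AKBA array only, which favours a value above 0 in the count and the median. The 19 genes with 1 detected probe stay open. A difference between the cultures other than AKBA cannot be told apart from the compound with 1 array per group. A response of the stress list to AKBA therefore stays a hypothesis, and whether amino acid shortage or another trigger raised it was not tested.

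The second pattern is the lower signal of DNA methylation genes. Without DNMT1, UHRF1 and HELLS, members tied to DNA replication, the list median was -0.21 over 11 genes, which still lay below the lower limit of -0.19 of its random lists, at the 1.56th percentile. Its resampled interval, from -0.41 to 0.25, reaches past that limit, so how much these 3 members add stays open. Culture differences stay open as above.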

How the results depend on the processing

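The settings that used brighter genes, left out shared members, counted relative to the median or used bounds were chosen after seeing the data, and with 1 array per group no replicate could be left out. No paired analysis was possible because each group has 1 array. Among 145 alternative values of the 12 lists that stood apart, 136 kept direction and side, and all alternatives of the stress list lay between 0.75 and 0.89. Canonical histones turned to -0.033 at a detection p under 0.05 and gave 0.017 without a filter on detection, 0.20 with the mean over probes and 0.23 among brighter genes. In each of these settings that list lay inside its random range, and it stood apart in 8 of 12 alternatives. Xenobiotic metabolism turned to -0.17 among brighter genes and gave 0.14 at p under 0.05 and 0.026 without a filter. Without a filter NRF2 targets gave 0.051 and Wnt targets -0.051. The causes were not tested. Of the lists that had not stood apart, 20 alternative values did, 4 of them of the chaperones. The DNA methylation median stayed below its random range, at -0.16 with the mean over probes and -0.15 without a filter, and that of epithelial genes was 0.17 and 0.15 there and 0.16 among brighter genes. The genes higher and lower by 2-fold numbered 20 and 4 with an offset of 50, 16 and 2 without background correction, 18 and 177 with median scaling, 11 and 2 among brighter genes, and 29 and 8 with bounds for genes detected on 1 array. At 1.5-fold they numbered 251 and 377 and at 3-fold 7 and 0. The authors' processed values gave 121 lower genes, and detection on both arrays gave 8. Same-gene probes past 2-fold had the same direction in 100% of 3 genes with an offset of 50, 100% of 3 without background correction and 100% of 15 with median scaling, in 83.3% of 12 at p under 0.05 and in 46.0% of 37 without a filter on detection. Of 618 alternative values of named genes, taken relative to the median of detected genes where a scaling shifted it, 0 turned direction and 32 moved beyond the spread between probes. Without taking off that shift, 3 genes turned with median scaling (ACTA2, H2BC11 and PTGES3) and 1 with the authors' values (ACTA2). Signal over background limits the dimmest genes, where the standard deviation of differences was 0.41 against 0.26 among the brightest.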

Other observations

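The tests of transfer RNA synthetases, transporters and detection were set before their results were seen, while the resampled intervals were added afterwards. Such intervals hold no spread between cultures. Transfer RNA synthetases of the cytosol outside the fixed list had a median difference of 0.15 over 13 genes, at the 97.4th percentile of random lists, and amino acid transporters outside it had 0.16 over 12 genes, at the 95.6th percentile; whether these groups shared the higher signal stays open. The synthetases of mitochondria had a median of -0.070 over 14 genes, with a resampled interval from -0.34 to 0.01 that ends below 0.17, the upper limit of random lists, which argues against a rise that includes them.

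The control array detected 661 genes that the AKBA array did not, and the AKBA array 48 that the control array did not. The AKBA array was dimmer, with a background-subtracted signal ratio of 0.792 over probes detected on both arrays. Dimming the control signals by that ratio put 549 genes under the AKBA array's detection limit, so lower brightness may account for much of the asymmetry.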
